A study of Mus musculus with 2 samples.

How the data were processed

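The data are 2 single-cell RNA sequencing libraries of CD45-positive, DAPI-negative cells sorted from mouse mammary tumours, 1 from the PyMT-M line and 1 from the PyMT-N line, made with the 10x Genomics 5′ chemistry per the labels' protocols. Each was deposited as a matrix of raw UMI counts per gene and barcode, with no normalisation. The matrices were written by software version 3.1.0, per the file headers. Per the submitters' processing notes, Cell Ranger and Seurat were used with build mm10, with versions not given in the sources used here. The lowest deposited count of a barcode was 501 UMIs in PyMT-M and 500 in PyMT-N. No annotation of cells by the authors was used here.

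Cells were kept with at least 200 genes and at most 10% mitochondrial UMIs, which removed 119 barcodes of PyMT-M and 26 of PyMT-N. Doublets were scored per library with Scrublet, run through scanpy 1.11.5 and anndata 0.12.19, at an expected rate of 0.8% per 1000 barcodes. The automatic threshold marked 0 cells, below the minimum of 0.5% set beforehand, so the planned fallback removed the cells with the highest scores up to the expected rate, 440 and 201 cells. The 6917 and 4793 cells left held 39365195 and 13943188 UMIs. Both libraries were clustered together without batch correction, on counts per 10000, log-transformed, with 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 1. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.

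Clusters were named from 20 sets of marker genes fixed before the data were examined. A name needed at least 3 of its markers, each seen in 10% of the cluster's cells, and among the 10 leading genes no more markers of another class than of its own. A cluster under 1/3 of its library's median UMIs with no own marker leading stayed unnamed. The rule for ranking classes was not fixed beforehand. In all, 3 rules were tried, each written after clusters had been seen, and the third after shares had been seen. The first took the best class only, with a minimum score of 0.25 and dendritic subsets kept apart, and the second tried up to 3 classes. Under both, a class with almost no detected marker could rank first and leave a cluster unnamed, which set the PyMT-N neutrophil-like share at 49.0%. The third rule, used throughout, ranks only classes with 3 detected markers and gave 70.2%. Leading genes of the dendritic cell-like cluster included markers of several dendritic subsets, so it was not divided.

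UMIs were summed over the cells of a class in each library and given as CPM. Gene ratios have exact conditional binomial intervals and summed levels exact Poisson intervals, shares have exact Clopper-Pearson intervals, and list medians have intervals from 1000 Poisson redraws, all at 95%. They cover counting error only. List members needed 20 UMIs over both libraries. For each of 18 lists fixed beforehand, the median was set against 10000 random lists matched on mean expression in 20 bins. Random members were drawn singly, whereas genes of a list can vary together. The percentile is therefore descriptive and measures no variation between cells or tumours. A list with under 3 measured genes in a class is not reported for that class. Genes at 0 in a library have a bound against a floor of 3 UMIs in the class. The share of interferon-high cells came from cells thinned to 1000 UMIs, with a threshold of 5 UMIs. Macrophage RNA in neutrophil-like cells was estimated from C1qa, C1qb and C1qc.

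Named genes followed a rule fixed beforehand: in each of 3 classes, up to 10 genes per direction with the largest ratio, among those with 100 UMIs, 50 CPM in the higher library, an interval end beyond 1.5-fold and a CPM of at least 0.5 of that in any other class of 50 or more cells. Mitochondrial, ribosomal, immunoglobulin, T cell receptor, haemoglobin and predicted genes were left out. List examples were the members with the highest CPM and the largest ratio, at most 4 per list and class. Other members given beside a list were chosen after their values were seen. Symbols shared by several gene identifiers were summed. Gene positions were taken from GENCODE annotation of GRCm38 by gene identifier, while the release the authors used is not given in the sources used here.

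The statistics were tested on simulated counts with 200 genes changed 4-fold in either direction, drawn from genes with 10 or more expected UMIs in each library. For the neutrophil-like comparison, run on 1204 genes, 99.5% of changed genes with 100 UMIs had the right direction and 95.4% of intervals covered the true ratio. For monocyte- and macrophage-like cells (10435 genes) the values were 100% and 95.3%, and for T cell-like cells (4634 genes) 100% and 96.1%. The simulated counts were Poisson draws, the model that the intervals assume, with no variation between cells or libraries. Coverage near 95% was therefore built in, and the simulation checks the calculation only. Counting the proliferating cluster, or its cells with a Cd3 UMI, as T cells was added after the lists had been seen. So were the Cd3 and Trac background and the NK cell-like share without that cluster. The summed interferon level without Ifi27l2a, or at a shared cluster mix (clusters with 20 cells in both libraries), was also added then. The alternatives fixed beforehand covered the cell filters, doublets, clustering, scaling, pseudocounts, thinning and thresholds. No test between the lines was made, because each has 1 library.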

Results

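Immune cells were profiled from mouse mammary tumours grown from either of 2 cell lines, PyMT-M and PyMT-N, whose names refer to the polyoma middle T oncogene used to model breast cancer. The labels do not say what the letters M and N stand for. Line cells were injected into the mammary gland and tumours were taken after 4 weeks, at a diameter of 0.7 to 1 cm. Living cells carrying CD45, the surface protein of blood-derived cells, were sorted and sequenced with a droplet method that reads the 5′ end of each transcript and counts unique molecular identifiers (UMIs). There was 1 library per line. The PyMT-M library held 7476 barcodes and 43977988 UMIs, with a median of 5069.5 UMIs per barcode, and the PyMT-N library held 5020 barcodes and 14907736 UMIs, with a median of 1955. After filters 6917 and 4793 cells were kept. With 1 library per line no test was possible, no difference has a replicate check, and each interval below is a 95% interval of counting error only. Cell classes were rebuilt from clusters and fixed markers, and are called "-like" for that reason. The ratios are log2 ratios of PyMT-N over PyMT-M counts per 1000000 UMIs (CPM) with a pseudocount of 1 CPM, and intervals of single genes are of the ratio without it, so that negative values mean a higher level in the PyMT-M tumour.

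The first comparison concerned which immune cells made up each tumour. Neutrophil-like cells, led by the alarmin genes S100a8 and S100a9, formed 70.2% of the PyMT-N library (68.9 to 71.5%, 3364 cells) and 0.723% of the PyMT-M library (0.537 to 0.952%, 50 cells). Monocyte- and macrophage-like cells showed the opposite order. They were at 76.4% in PyMT-M (75.4 to 77.4%, 5283 cells) and 21.7% in PyMT-N (20.5 to 22.9%, 1039 cells). The 3364 neutrophil-like cells of PyMT-N, against 50 in PyMT-M, lower every other share in PyMT-N. The opposite order is therefore not a separate sign of fewer cells of the monocyte- and macrophage-like class in PyMT-N. Within that class, macrophage-like cells, led by Apoe and the complement genes C1qa, C1qb and C1qc, were 70.0% of PyMT-M and 13.8% of PyMT-N cells. Monocyte-like cells were at 6.38% and 7.84%. They were cluster 7 (246 PyMT-M and 321 PyMT-N cells) and cluster 16 (195 and 55 cells). Cluster 16 had 4 detected monocyte markers and a score of 0.24, and stayed unnamed under the first naming rule, so the monocyte-like shares are uncertain.

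Lymphoid cells were a larger part of the PyMT-M library, but the many neutrophil-like cells of PyMT-N lower every other share there. T cell-like cells made up 8.39% of PyMT-M cells (7.74 to 9.06%) and 3.21% of PyMT-N cells (2.73 to 3.75%). Natural killer (NK) cell-like cells, led by the granzyme genes Gzma and Gzmb, were at 7.95% and 1.38%, or 6.25% (5.69 to 6.84%) and 0.522% (0.338 to 0.769%) without the proliferating cluster 21, in which many cells carried Cd3 RNA. B cell-like cells were at 0.810% (0.612 to 1.05%, 56 cells) and 1.502% (1.18 to 1.89%, 72 cells), dendritic cell-like cells at 1.91% and 1.13%, and mature dendritic cell-like cells at 0.405% and 0.167%. Epithelial or tumour cell-like cells were at 3.44% and 0.751% in spite of the CD45 sort, but were not alike. Wfdc18 and the secretoglobin genes that led this class in PyMT-M had 0 CPM in the 36 PyMT-N cells, which held keratin Krt18 at 831 CPM and Mgp at 4026 CPM. At resolution 2 the clusters led by Wfdc18 or secretoglobin genes held 0 PyMT-N cells, and 42 PyMT-M and 35 PyMT-N cells lay in a cluster named fibroblast. With each library clustered alone, 36 PyMT-N cells were named epithelial or tumour cell and 29 PyMT-M cells endothelial cell, so the class name is uncertain in both libraries. The doubt bears mainly on cluster 19, whose 131 PyMT-M cells held Sparc at 3017 CPM and Plvap at 1081 CPM. Cluster 23, with 107 PyMT-M cells, held Epcam at 1897 CPM, Krt18 at 2480 CPM and Sparc at 56.3 CPM. The order of some classes depends on the neutrophil-like cells. Set against the 5283 PyMT-M and 1039 PyMT-N monocyte- and macrophage-like cells, T cell-like (580 and 154) and dendritic cell-like cells (132 and 54) were more frequent in PyMT-N. NK cell-like cells (550 and 66) were still more frequent in PyMT-M. All shares are of sorted cells with at least 500 UMIs, so the sort and that floor can set them. The gap in UMIs per cell between the libraries was small within the 2 largest classes: neutrophil-like cells had medians of 1642 UMIs in PyMT-M and 1674 in PyMT-N, and monocyte- and macrophage-like cells 4927 and 5016. Other classes were deeper in PyMT-M, such as T cell-like cells at 3935.5 and 2519 and dendritic cell-like cells at 7075.5 and 5853.5, so the cell mix is not the whole gap. The PyMT-N neutrophil-like share was 49.0% under each of the 2 earlier rules for naming clusters.

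**Figure D1:**
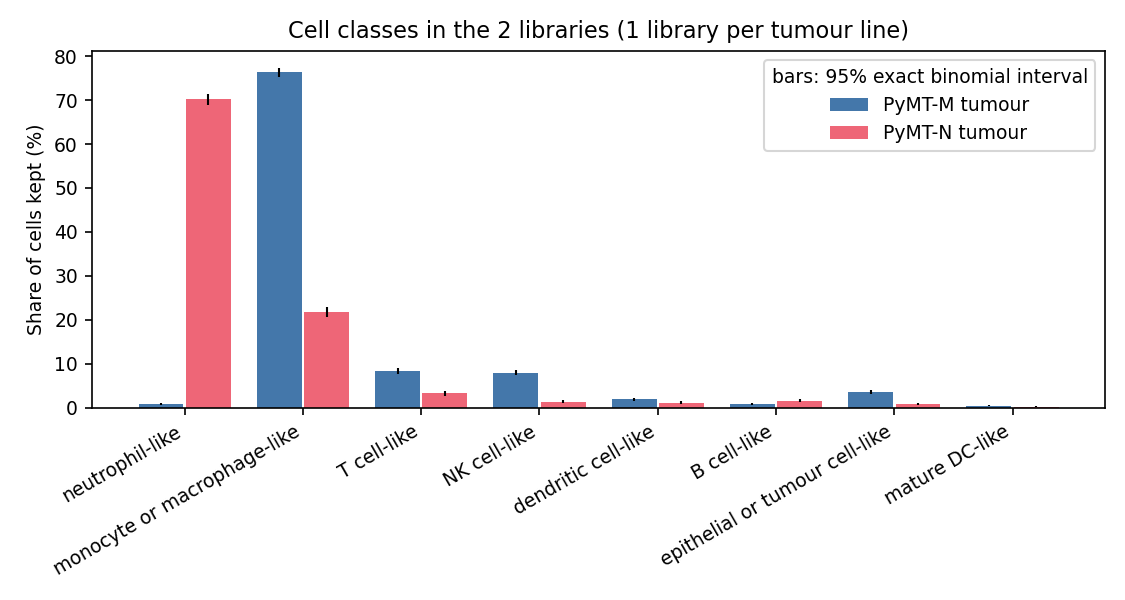
Share of the cells kept, in percent, for each class, with 1 bar per library and 95% exact binomial intervals. Neutrophil-like cells stand at 70.2% in PyMT-N and 0.723% in PyMT-M, and monocyte- and macrophage-like cells at 21.7% and 76.4%.

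The title of the series names interferon-stimulated neutrophils, so the next comparison concerned the response to type I interferon, the antiviral cytokine family, within neutrophil-like cells. Interferon-stimulated genes were higher per UMI in the few PyMT-M neutrophil-like cells than in those of PyMT-N. Of the 31 measured members of the list, 19 were at least 2-fold higher in PyMT-M and 0 were at least 2-fold higher in PyMT-N. Isg15, a ubiquitin-like protein induced by interferon, was at 1425.5 CPM in PyMT-M and 527 CPM in PyMT-N, a log2 ratio of -1.43 (-1.69 to -1.17). Ifi27l2a was at 2508.5 and 1290.3 CPM (log2 ratio -0.96). Usp18, a protease that removes ISG15 from proteins, had a log2 ratio of -2.17 and Ifit2 one of -2.31, on 7 and 4 UMIs in PyMT-M.

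The median log2 ratio over the type I list was -1.34 (-1.46 to -1.01), at percentile 0 of 10000 random lists matched on mean expression. That percentile covers no variation between cells or tumours. Summed over the list, 86.9 of 10000 neutrophil-like UMIs in PyMT-M (80.9 to 93.1) and 39.4 in PyMT-N (38.9 to 39.9) came from these genes. The largest single cluster of PyMT-M neutrophil-like cells was cluster 5 (20 of 50 cells) and that of PyMT-N cluster 1 (30.1%). Macrophage RNA made up an estimated 7.39% of the PyMT-M neutrophil-like UMIs and 0.319% of those of PyMT-N. With the class taken cell by cell from marker expression in place of clusters, the median was -0.79 (-0.96 to -0.52). Isg15 (ENSMUSG00000035692) is annotated on chromosome 4, positions 156199424 to 156200818, and Ifi27l2a (ENSMUSG00000079017) on chromosome 12, positions 103442167 to 103443680, of build GRCm38.

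Single cells showed the same order. After each cell was thinned to 1000 UMIs, 23 of 45 PyMT-M neutrophil-like cells held 5 or more type I interferon UMIs, a share of 51.1% (35.8 to 66.3%). In PyMT-N 729 of 3146 did, a share of 23.2% (21.7 to 24.7%). These are ranges of a continuous count and not cell types: 8.89% and 9.44% of cells lay at 4 or 5 UMIs. By number, then, PyMT-N held most of the interferon-high neutrophil-like cells. The same range held 48.6% of PyMT-M and 25.5% of PyMT-N T cell-like cells, and 10.7% and 19.7% of B cell-like cells, whose intervals overlap. Cells under 1000 UMIs, 5 in PyMT-M and 218 in PyMT-N, were left out. Without thinning the neutrophil-like shares were 52.0% and 20.4%.

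**Figure D2:**
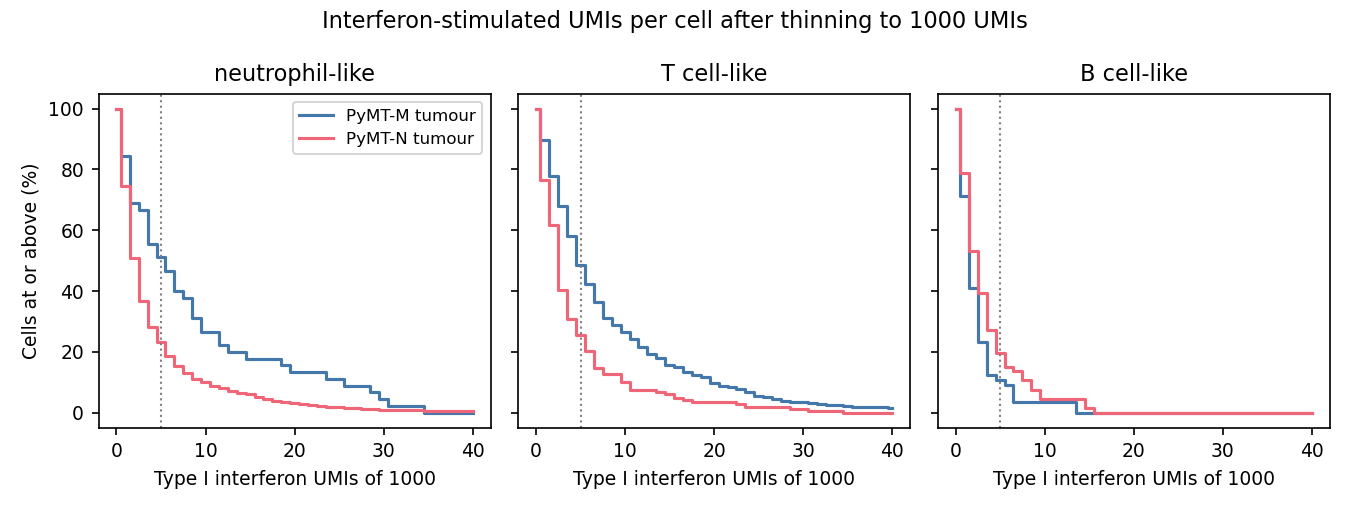
Percent of cells at or above each number of type I interferon UMIs after thinning to 1000 UMIs, for neutrophil-like, T cell-like and B cell-like cells, 1 line per library, with a dotted line at 5 UMIs. At that line PyMT-M stands at 51.1% and PyMT-N at 23.2% of neutrophil-like cells.

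Hypoxia and glycolysis genes were higher in the PyMT-N neutrophil-like cells. Of 23 measured members, 17 were at least 2-fold higher in PyMT-N and 0 in PyMT-M, with a median log2 ratio of 1.68 (1.25 to 1.89), or 1.22 with genes at 0 set to a floor of 3 UMIs. Gapdh, a glycolytic enzyme, was at 6586 CPM in PyMT-N and 895 CPM in PyMT-M (log2 ratio 2.88), and the cytokine gene Mif had a log2 ratio of 1.68. Genes of neutrophil granules were split: Lcn2, an iron-scavenging protein, had a log2 ratio of 1.33, while Retnlg had one of -0.14 (-0.29 to 0.02). The granule list's median was 0.28, with an interval that includes 0 (-0.16 to 1.57), and -0.09 with genes at the floor.

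The myeloid suppressor list had a median of 0.33 (0.16 to 0.84) in neutrophil-like cells, with Wfdc17 at 1.07 and the receptor gene Clec4e at 0.66. The tumour-associated neutrophil list lay at -0.41 (-0.51 to 0.16), with its members divided: the chemokine gene Ccl4 had a log2 ratio of -1.39, Hilpda, a lipid droplet gene, 1.04, and Vegfa, a vascular growth factor, 2.66 (0.85 to 5.76, on 2 UMIs in PyMT-M). Inflammatory cytokines and chemokines were at -0.69 (-0.86 to -0.48), with Il1b at -0.58 and Cxcl2 at -0.42. Interferon-gamma-responsive genes were at -0.64 (-1.29 to -0.30), and the list of dissociation and heat-shock stress at -0.78 (-0.85 to -0.65). MHC class I genes were at -0.59, with H2-D1 at -1.32 and B2m at 0.22. MHC class II genes (-4.99) and resident macrophage genes (-3.85) were far higher in PyMT-M neutrophil-like cells, where macrophage RNA was also more abundant. For example, Cd74 was at 4044.5 and 88.8 CPM, and C1qb at 840 and 13.4 CPM. The lipid-associated macrophage list lay at 0.20 (-0.26 to 0.43), but its most abundant member, Apoe, had a log2 ratio of -4.59. Lists of T cell genes had at most 5 measured members in these cells: exhaustion was at -0.10, naive and memory at -1.30 and regulatory T cell at 3.06, or -0.25 with genes at the floor.

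By the fixed rule for single genes, those highest in PyMT-N neutrophil-like cells had 0 UMIs in PyMT-M, so that their folds are lower bounds against 3 UMIs in the class. Ngp, a granule protein of immature neutrophils, was at 802 CPM and at least 24.2-fold higher. Prok2, a secreted peptide made by neutrophils, was at least 11.2-fold higher, BC100530 at least 7.02-fold, Camp, the cathelicidin gene, at least 6.47-fold, and Nos2, the inducible nitric oxide synthase, at least 3.39-fold. Hspa1a, Pdcd1lg2 (which encodes PD-L2), Stfa2, Smim27 and Ambp were at least 2.71-, 2.44-, 2.37-, 2.11- and 2.05-fold higher. In the other direction, Inhba, an activin subunit, had a log2 ratio of -3.48 (-4.34 to -2.71, 16 UMIs in PyMT-M), Jaml -3.17, Scnn1a -2.93 and Pacsin2 -2.84. The chemokine gene Cxcl10 was at -2.80 (-3.50 to -2.09), Rcan1 at -2.76, the interferon-induced GTPase gene Igtp at -2.58, Ccdc86 at -2.52, the chemokine gene Ccl6 at -2.29 (198 UMIs) and Nat6 at -2.22. The PyMT-M class held 90494 UMIs against 6651841 in PyMT-N, which limits what could be detected there. The lower bounds treat UMIs as independent and leave out the sampling of only 50 PyMT-M cells. At resolution 2, a cluster with Ngp and Camp among its leading genes held 53 PyMT-N and 0 PyMT-M cells. For genes concentrated in few cells, 0 UMIs in PyMT-M may thus reflect the few cells sampled, and the bound may not hold. Ngp (ENSMUSG00000032484) is annotated on chromosome 9, positions 110419747 to 110423012, and Inhba (ENSMUSG00000041324) on chromosome 13, positions 16011851 to 16031621, of GRCm38.

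**Figure D3:**
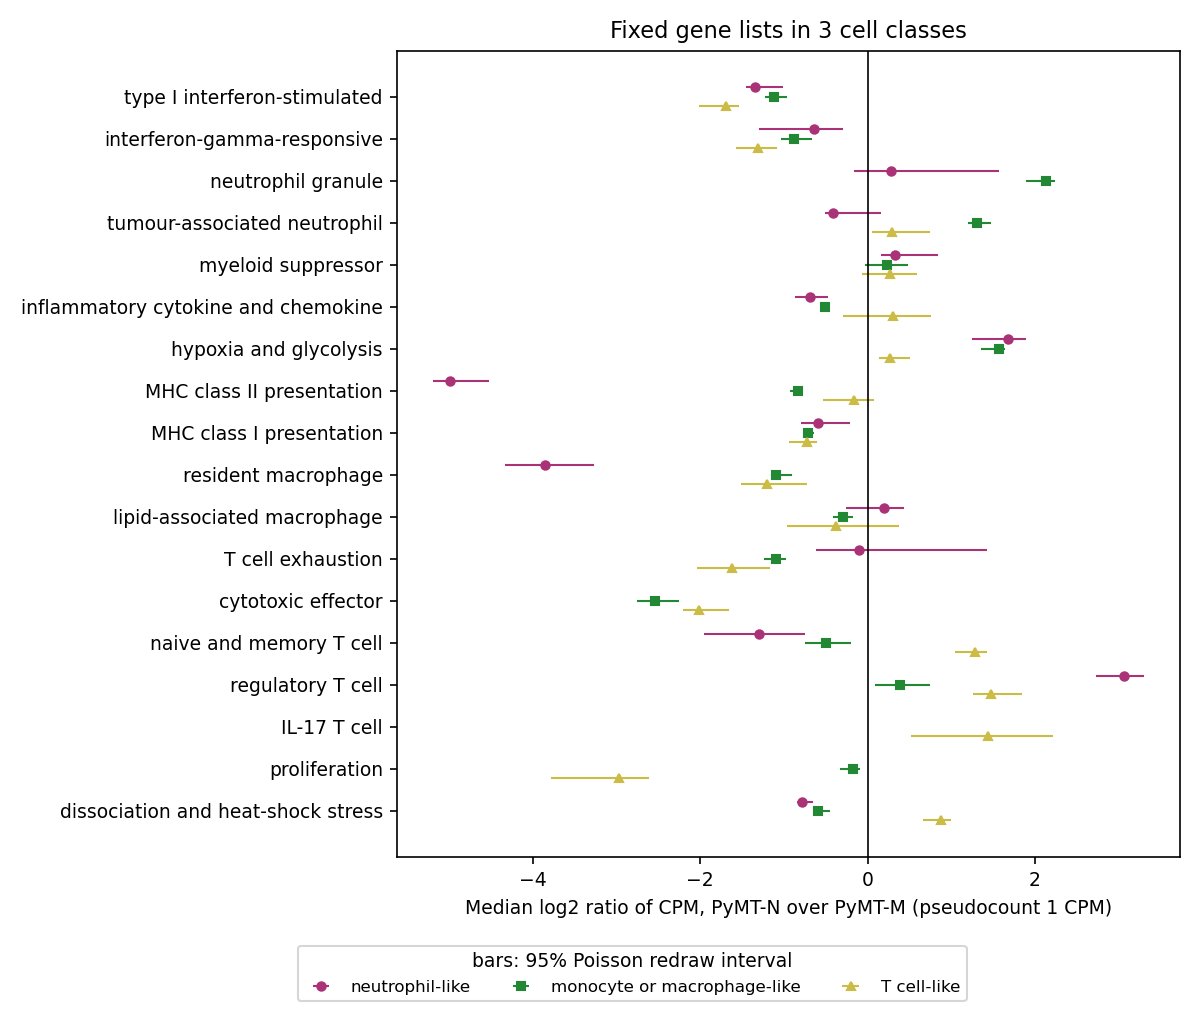
Median log2 ratio of CPM, PyMT-N over PyMT-M, of each fixed gene list in neutrophil-like, monocyte- and macrophage-like and T cell-like cells, with 95% intervals from redrawn counts. The type I interferon list lies left of 0 in the 3 classes, at -1.34, -1.12 and -1.69, and the hypoxia and glycolysis list right of 0, at 1.68, 1.57 and 0.27.

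Monocyte- and macrophage-like cells differed between the tumours in metabolism, antigen presentation and tissue-resident genes. Resident macrophage genes were higher in PyMT-M, with a median log2 ratio of -1.10 (-1.13 to -0.90) and 8 of 15 members at least 2-fold higher. C1qb was at 11137 CPM in PyMT-M and 3217 CPM in PyMT-N (log2 ratio -1.79), and Cd209f had a log2 ratio of -3.19. MHC class II genes lay at -0.83 (-0.93 to -0.80), with the invariant chain gene Cd74 at -1.17 and H2-Eb1 at -1.05. Hypoxia and glycolysis genes were higher in PyMT-N, at 1.57 (1.35 to 1.64), with 12 of 23 at least 2-fold higher and 0 the other way. Gapdh was at 2923 CPM in PyMT-N and 515 CPM in PyMT-M, and Ldha had a log2 ratio of 0.53 and Ndrg1 of 3.58. The largest clusters of the class in PyMT-M were the macrophage-like clusters 0 (28.7%) and 2 (18.7%), and in PyMT-N the macrophage-like cluster 10 (33.0%) and the monocyte-like cluster 7 (30.9%), so the values compare different mixes. The median log2 ratio over all genes with 100 or more UMIs was -0.20 in this class.

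Interferon genes of this class were mostly higher in PyMT-M as well. The type I list had a median of -1.12 (-1.23 to -0.96), with 20 of 36 members at least 2-fold higher in PyMT-M and 3 in PyMT-N. Bst2, a restriction factor against enveloped viruses, had a log2 ratio of -1.71 and Ifit3b one of -2.44, while Ifi27l2a, at 1.03, and Slfn4, at 2.79, were higher in PyMT-N. The summed level differed little, at 55.4 of 10000 UMIs in PyMT-M (55.2 to 55.7) and 50.2 in PyMT-N (49.6 to 50.8). Without Ifi27l2a it was 38.9 (38.6 to 39.1) and 16.4 (16.0 to 16.7), and with 7 shared clusters set to the PyMT-M mix it was 59.5 and 38.3 over all genes. Interferon-gamma-responsive genes lay at -0.88 (-1.03 to -0.67), with the T cell attracting chemokine gene Cxcl9 at 68.6 CPM in PyMT-M and 7.13 CPM in PyMT-N, and Irf8 at -1.20. MHC class I genes were at -0.71, inflammatory cytokines and chemokines at -0.51, and stress genes at -0.60. The myeloid suppressor list lay at 0.24 (-0.03 to 0.49) and the lipid-associated macrophage list at -0.29 (-0.41 to -0.17), with Apoe at -2.18 and Fabp5, a fatty acid binding protein, at 2.56. The proliferation list lay at -0.18, and at 0.0195 with median ratio scaling. Lists of neutrophil granule (2.13) and tumour-associated neutrophil genes (1.31) were higher in PyMT-N. Neutrophil RNA was also present in these cells, with S100a8 at 338 CPM in PyMT-N and 3.55 CPM in PyMT-M. Whether that RNA accounts for either list was not tested. Lists of T cell genes, which can come from free RNA in this class, lay at -1.09 for exhaustion, -2.54 for cytotoxic effector, -0.50 for naive and memory and 0.39 for regulatory genes.

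By the fixed rule, the gene with the largest ratio in PyMT-N in this class was a protease gene. Ctsk, a collagen-degrading protease, was at 164 CPM in PyMT-N and 0.171 CPM in PyMT-M, from 918 and 5 UMIs. The log2 ratio was 7.14, and 8.68 to 11.53 is the interval without the pseudocount. Mmp12, macrophage elastase, had a log2 ratio of 4.78, the metallothionein gene Mt3 4.69, S100a4 3.32, Plac8 3.23, Ly6c2, a monocyte surface gene, 2.99, Sys1 2.74, Mmp13, a collagenase, 2.43 and the heat-shock gene Hspa1a 2.36. Klra17, a gene of the killer lectin-like receptor family, was highest in PyMT-M, at 237 and 4.28 CPM, with a log2 ratio of -5.49 (-6.43 to -5.22 without the pseudocount). H2-M2 was at -5.46, Fcrl5 at -4.97, Camk2n1 at -3.75, Gpr31b at -3.62, Tnfsf13b, which encodes the B cell factor BAFF, at -3.27, Asb2 at -3.23, Il18bp, an inhibitor of interleukin 18, at -3.18 and Ccl4 at -3.03. Ctsk (ENSMUSG00000028111) is annotated on chromosome 3, positions 95499256 to 95509362, and Klra17 (ENSMUSG00000014543) on chromosome 6, positions 129831154 to 129876672, of GRCm38.

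T cell-like cells of the PyMT-M tumour carried more RNA of cytotoxic and CD8 cells, and those of PyMT-N more of regulatory and interleukin 17 cells. Cytotoxic effector genes had a median log2 ratio of -2.01 (-2.20 to -1.66), with 11 of 13 at least 2-fold higher in PyMT-M. It was -0.94 with the proliferating cluster 21, named NK cell-like, counted as T cells. Nkg7 was at 2923 CPM in PyMT-M and 467 CPM in PyMT-N (log2 ratio -2.64), and Gzmk, a granzyme, was at 334 and 6.68 CPM (-5.45, on 916 and 3 UMIs; -7.93 to -4.09). Exhaustion genes lay at -1.62 (-2.04 to -1.17), with the inhibitory receptor gene Tigit at -1.48 and Lag3 at -4.04 (-7.37 to -2.45 without the pseudocount, on 2 UMIs in PyMT-N). The proliferation list had a median of -2.97 (-3.78 to -2.61), but this value depends on the naming of the proliferating cluster 21. That cluster made up 62.1% of PyMT-N and 21.5% of PyMT-M NK cell-like cells, and 30 of its 41 PyMT-N cells and 62 of its 118 PyMT-M cells had a UMI of Cd3d, Cd3e or Cd3g. At 1000 UMIs per cell these shares were 65.9% (49.4 to 79.9%) in PyMT-N and 39.8% (30.9 to 49.3%) in PyMT-M, against 12.0% (2.55 to 31.2%) and 18.5% (14.97 to 22.6%) of other NK cell-like cells and 0% of B cell-like cells. A Cd3 UMI therefore does not by itself mark a T cell. At the same depth, a UMI of the T cell receptor gene Trac was in 19.5% (8.82 to 34.9%) of the cluster's PyMT-N and 10.2% (5.37 to 17.1%) of its PyMT-M cells. These shares lay between other NK cell-like cells, at 0% (0 to 13.7%) and 1.17% (0.382 to 2.72%), and T cell-like cells, at 27.5% and 27.4%. With the cluster counted as T cells the proliferation median was 0.21 (0.07 to 0.32). With only its Cd3 cells added it was 0.32 (0.15 to 0.45), so no difference in T cell proliferation can be stated.

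Regulatory T cell genes were higher in PyMT-N, at 1.48 (1.25 to 1.84), with 9 of 10 at least 2-fold higher. Foxp3, the lineage factor of regulatory T cells, had a log2 ratio of 3.49 (2.89 to 4.43 without the pseudocount) and the costimulatory receptor gene Tnfrsf4 one of 3.44. The interleukin 17 list lay at 1.44 (0.51 to 2.21), with the cytokine gene Il17a at 2.33. Naive and memory genes lay at 1.29 (1.04 to 1.43), with Klf2 at 1.16, the cytokine receptor gene Il7r at 2.18 and Bcl2, which differed in sign, at -0.92. A UMI of Cd8a was found in 60.5% of PyMT-M and 9.74% of PyMT-N T cell-like cells, and one of Foxp3 in 1.55% and 18.2%. B cell-like cells gave 0% for both genes in both libraries. Median depths were 3935.5 and 2519 UMIs in T cell-like and 1915 and 1567.5 in B cell-like cells.

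The type I interferon list of T cell-like cells had a median of -1.69 (-2.02 to -1.54), with 26 of 32 members at least 2-fold higher in PyMT-M and 0 in PyMT-N. Isg15 had a log2 ratio of -1.66, and Usp18, with 0 UMIs in PyMT-N, was at least 8.96-fold higher in PyMT-M. Interferon-gamma-responsive genes lay at -1.31 (-1.58 to -1.08), and Cxcl10, also at 0 UMIs in PyMT-N, was at least 18.4-fold higher in PyMT-M. MHC class I genes were at -0.73, hypoxia and glycolysis genes at 0.27 and stress genes at 0.87. Lists of macrophage genes, also open to free RNA, lay at -0.16 for MHC class II, -1.20 for resident and -0.37 for lipid-associated macrophages. The inflammatory list (0.30), the tumour-associated neutrophil list (0.29) and the myeloid suppressor list (0.27) lay near 0, and the second of these was -0.27 with cluster 21 counted as T cells. Within the first, Cxcl2, a gene abundant in neutrophils, had a log2 ratio of 4.71, while S100a8 was at 218 CPM in PyMT-N and at 0 in PyMT-M T cell-like cells. PyMT-M T cell-like cells lay mostly in clusters 15 (41.6%) and 17 (38.6%), and those of PyMT-N in clusters 20 (59.1%) and 24 (24.7%). Cluster 17, with 224 PyMT-M and 0 PyMT-N cells, may be an effect of that library. Its leading genes included Nkg7, Cd8a, Cd8b1 and Trbv13-1, so the PyMT-M levels of these genes rest in part on it. In clustering without the interferon lists, the cluster with the same leading genes (229 PyMT-M cells) held 96.0 type I interferon UMIs of 10000. PyMT-M cells of the T cell-like clusters 11 and 18 of that clustering held 52.5 and 76.3. The median over all genes in T cell-like cells was -0.21.

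Among single genes by the fixed rule, Il2ra, a chain of the interleukin 2 receptor, had a log2 ratio of 3.42 in T cell-like cells, S100a4 3.099, the transcription factor genes Maf and Rora 3.03 and 2.58, Nme1 2.23, and Tmem64 1.99. The costimulatory gene Icos was at 303 CPM in PyMT-N and 74.8 CPM in PyMT-M. Higher in PyMT-M were the coreceptor genes Cd8a at -3.75 and Cd8b1 at -3.21, and, with cluster 21 left out, the cell cycle genes Ube2c at -3.91, H2afx at -2.92, Birc5 at -2.88 and Ccnb2 at -4.06 (-9.88 to -2.07 without the pseudocount, on 1 UMI in PyMT-N). With that cluster counted as T cells these 4 ratios were 0.0747, -0.0876, 0.27 and -0.45, so that Ube2c and Birc5 changed direction and the other 2 moved towards 0. Cd8a (ENSMUSG00000053977) is annotated on chromosome 6, positions 71373427 to 71379173, and Foxp3 (ENSMUSG00000039521) on chromosome X, positions 7573644 to 7595245, of GRCm38.

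**Figure D4:**
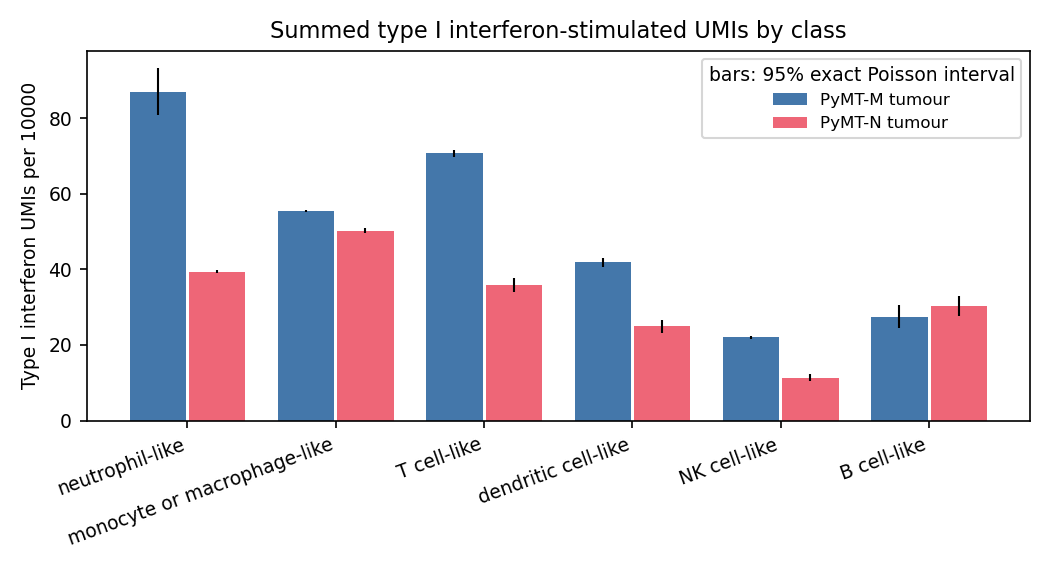
Type I interferon UMIs per 10000 UMIs in each class, 1 bar per library, with 95% exact Poisson intervals. Neutrophil-like cells stand at 86.9 in PyMT-M and 39.4 in PyMT-N and T cell-like cells at 70.7 and 35.9, while B cell-like cells stand at 27.4 and 30.2.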

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

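The naming rules, the proliferating cluster or its Cd3 cells as T cells, the C1q-free cells and the macrophage subtraction were alternatives chosen after seeing the data. The type I interferon median in neutrophil-like cells stayed negative in each alternative run. It was -1.48 as a mean over cells of counts per 10000, -1.52 in cells with no C1q UMI and -0.79 with the class taken per cell. The neutrophil-like share stayed higher in PyMT-N in each alternative, at 49.0% of PyMT-N under the first and under the second naming rule and 71.6% with a mitochondrial limit of 5%. The first naming rule gave 73.6% monocyte- and macrophage-like cells in PyMT-M, and T cell-like shares of 7.33% in PyMT-M and 1.31% in PyMT-N. Classes taken per cell gave 77.6% monocyte- and macrophage-like cells in PyMT-M. Counting the proliferating cluster as T cells gave T cell-like shares of 10.1% and 4.07%. With the whole cluster, and then with only its Cd3 cells, the T cell-like proliferation median turned to 0.21 and 0.32, the tumour-associated neutrophil median to -0.27 and -0.22, Ube2c to 0.0747 and 0.16 and Birc5 to 0.27 and 0.41. Without a change of direction, the cytotoxic median moved to -0.94 and -1.27, regulatory to 1.03 and 0.94, naive and memory to 1.01 and 0.98 and hypoxia to 0.52 and 0.59. The interferon-high share of neutrophil-like cells was 66.7% in PyMT-M and 36.6% in PyMT-N at a threshold of 3 UMIs, and 26.7% and 9.95% at 10 UMIs. In PyMT-N it was 21.6% when thinned to 500 UMIs with a threshold of 3, 20.4% unthinned and 30.3% under the second naming rule. Median ratio scaling gave type I medians of -0.92 in monocyte- and macrophage-like and -1.48 in T cell-like cells, a hypoxia median of 1.77 in the former and a naive and memory median of 1.49 in the latter. It turned the proliferation median of monocyte- and macrophage-like cells from -0.18 to 0.0195, which follows from the shift of -0.20 that it removes. Otherwise the cause was not tested. Of 280 alternatives for single named genes, 225 stayed within the counting interval, 51 moved beyond it and 4 changed direction. Genes at 0 UMIs in a library had an interval without an upper or a lower end, so staying within it says little about them. The 50 neutrophil-like cells of PyMT-M limit every value of that class.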

Other observations

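The tests of macrophage RNA, of C1q-free cells, of the UMI floor, of loss before sequencing and of the B cell-like cells were chosen after the results they bear on had been seen, as were the values of this first paragraph. In clusters found without the interferon lists and numbered anew, the summed type I interferon UMIs of monocyte- and macrophage-like cells differed in either direction. The sums of cluster 6 were alike, at 86.4 of 10000 in PyMT-M (85.1 to 87.7) and 86.6 in PyMT-N (85.3 to 87.9), while single members in it were higher in PyMT-M, such as Isg15 at 661 and 294 CPM and Rsad2 at 90.4 and 42.7 CPM. The sums were higher in PyMT-M in clusters 2 (54.2 and 22.96), 4 (53.6 and 21.0), 9 (35.2 and 22.9), 10 (48.2 and 17.1) and 12 (102 and 89.7). They were higher in PyMT-N in cluster 13, at 32.9 (32.0 to 33.8) and 52.4 (50.2 to 54.7). Single members in that cluster were again higher in PyMT-M, with Isg15 at 105 and 74.5 CPM, Ifit1 at 13.6 and 10.3 CPM and Rsad2 at 16.3 and 5.14 CPM. The higher sum in PyMT-N therefore does not hold for each member. Neutrophil-like cluster 3 gave 78.1 in PyMT-M (68.8 to 88.2, 23 cells) and 51.1 in PyMT-N (50.1 to 52.0). Within PyMT-N, neutrophil-like clusters ranged from 21.95 in cluster 1 to 61.5 in cluster 14, which was rich in the granule genes Retnlg and Ngp. NK cell-like cells were at 21.98 in PyMT-M and 11.3 in PyMT-N and dendritic cell-like cells at 41.9 and 24.9. B cell-like cells, at 27.4 (24.6 to 30.5) and 30.2 (27.7 to 32.9), were not higher in PyMT-M. Mature dendritic cell-like cells were at 51.4 (48.0 to 54.9) and 52.5 (45.9 to 59.9). These rest on only 28 PyMT-M and 8 PyMT-N cells, too few to tell whether the class differs.

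Among T cell receptor beta V segments in T cell-like cells, Trbv13-1 held 32.5% (31.0 to 34.0%) and Trbv1 27.3% of such UMIs in PyMT-M, while the most frequent segment in PyMT-N, Trbv3, held 12.95% (9.53 to 17.0%). Trbv13-1 was among the leading genes of cluster 17 of the main clustering, which held 224 PyMT-M and 0 PyMT-N cells. Segments share sequence, so single assignments are uncertain.

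The type I interferon list was higher in PyMT-M neutrophil-like cells. Macrophage RNA and cells holding it were argued against as explanations, while depth was tested only in part and the cluster mix was not settled. After the macrophage profile was subtracted the median log2 ratio was -1.40 (-1.51 to -1.01), and among cells with no C1q UMI, 40 in PyMT-M and 3253 in PyMT-N, it was -1.52 (-1.73 to -1.27). At 1000 UMIs per cell it was -1.21 (-1.33 to -0.61), and with 4 neutrophil clusters weighted alike -1.32 (-1.49 to -1.05). As a hypothesis, the rare neutrophils of the PyMT-M tumour may have met more interferon than those of PyMT-N, but a difference between lines and one between single libraries stay open and untested. Further tumours of each line, with 1 library per tumour, would tell these apart.

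The neutrophil-like share was far higher in PyMT-N. Loss of shallow cells at the floor of 500 UMIs is argued against, since 10.0% of the PyMT-M neutrophil-like cells (3.33 to 21.8%) and 6.48% of those of PyMT-N had fewer than 1000 UMIs. S100a8 and S100a9 in T, B and NK cell-like cells were 49.6 times as high in PyMT-N, at 8.47 of 10000 UMIs against 0.171, which argues against lysis of many PyMT-M neutrophils after the sort. A loss before the sort leaves no such trace, so it cannot be told apart from a tumour with few neutrophils, and as a hypothesis, a difference between the lines may account for the share. Counting neutrophils in sections of undissociated tumours would decide it.

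The type I interferon list was also higher in PyMT-M T cell-like cells. At 1000 UMIs per cell the median was -2.14 (-2.41 to -1.67), so a greater weight of deeper cells did not set it. Thinning keeps each cell's mix of genes on average, so that value cannot decide on other effects of depth. The cluster mix is argued against by -1.37 (-1.70 to -1.06) over the 2 clusters with enough cells in both libraries, which leaves out the cluster found in PyMT-M alone. A shift of the whole library cannot be told apart from a T cell difference: the B cell-like median was -0.42 (-1.44 to -0.02), but it rests on 7 genes, and the B cell-like sums, whose intervals overlap, ran the other way. As a hypothesis, several cell classes of the PyMT-M tumour may share an interferon response, which libraries of further tumours of each line would test against a library effect.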
